A study of Mus musculus with 8 samples.

How the data were processed

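Polyadenylated RNA from cultures described as osteoblasts of the mouse calvaria, the bony skull cap, was sequenced in 8 libraries. Group and number came from the sample titles, which give 4 controls and 4 knockouts, each numbered 1 to 4. The labels' protocols name a column kit sold for plant RNA and a dual-mode mRNA library kit. They do not say whether the counting used strand, which gene annotation was counted or how reads with several alignments were treated. The values the authors deposited are whole-number counts of reads per gene symbol, and nothing in the values points to an earlier normalization. Per the submitters' processing notes, STAR 2.7.11b and featureCounts 2 were used with the genome build named GRCm38 or mm10.

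The count table holds 25239 gene symbols. Total counts ran from 14347495 to 19065421 per library. Of the symbols, 24321 (96.4%) matched exactly 1 gene of GENCODE mouse release M21, which gave coordinates on GRCm38, transcript lengths and GC contents. Because strand use is not given in the sources used here, reads from a gene and an overlapping antisense gene cannot be told apart. Ribosomal protein genes and other families with processed pseudogenes are uncertain for the same kind of reason. Within each group, pairs of libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 8.56 to 307 over genes with at least 20 counts in a pair, so every library was counted as its own sample. The labels do not say how many animals stand behind a library, so p-values measure the spread between these libraries, which may be partly technical.

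The comparison was made with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 12837 genes, libraries were scaled with TMM factors, and the quasi-likelihood F test with robust dispersion was applied to a model of genotype alone. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values (read counts divided by the scaled library size) were computed here from the deposited counts with the TMM factors, and log2 CPM used a prior count of 2. Single genes were also compared with an exact two-sided permutation test of log2 CPM. The 37 gene lists were fixed before the data were examined, and the 30 with at least 5 tested members were tested with limma 3.58.1 camera on voom values, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With voom weights the p-values of the last pair of tests depend on the order in which libraries are entered, here controls first. In 3 orders tried, with and without a block, the estimated correlation gave 0 lists, and with the block fry gave 1, 1 and 0, so no statement rests on a fry call.

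Same-numbered libraries of the 2 groups were checked for pairing before the calls of different models were compared. After each group's mean was removed, same-numbered libraries correlated across genes with r of 0.460 to 0.829, and 6 of 8 libraries correlated best with their own number. Among the libraries numbered 1 to 3 the correlations were 0.145 to 0.369, and 6 of 6 correlated best with their own number. All were above the minimum of 0.1, so the numbers were taken to pair the libraries, from the data and not from any label, and results with the number as a block are given where they change a call. With all 8 libraries, unlike numbers among 1 to 3 also correlated, with r of 0.416 to 0.572, so the minimum does not test pairing there. Among numbers 1 to 3 alone unlike numbers gave −0.263 to −0.012. With so few libraries such a match can arise by chance, so the pairing is an assumption of every result with the block.

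The genes named were chosen by a rule written before the data were examined. It takes Sphk2, Sphk1, Sp7, Runx2, Cxcl12 and Csf3, then up to 10 genes per direction past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups. Where fewer than 5 pass, it takes the 5 with the smallest unadjusted p in each direction, and it adds up to 4 members with the smallest unadjusted p from each list described. No gene met the second part, so after seeing the data that part was also applied to the model with the block, with the same direction in 4 of 4 pairs in place of no overlap. There 308 genes met it. The list part was applied, by a choice made after seeing the data, to the 6 lists past the threshold without the block and to the sphingolipid, osteoblast, macrophage and monocyte, osteoclast and niche lists. The members it takes from lists given by a sum or a test alone, such as the collagen and matrix list, are mostly not named. Other genes named were chosen after their values were seen, and 1 further gene that the rule takes is not reported here.

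The code was tested on simulated counts with 200 changed genes, drawn with the real library sizes and the mean of the libraries sharing a number. Dispersions came from the fit with the block, and each change was alike in every pair. The gain from the block was thus built in, and the simulation does not test whether the real libraries are paired. Among 12715 simulated genes tested, the model without a block called 0% of genes changed 1.5-fold, 13.6% of those changed 2-fold and 75.8% of those changed 4-fold, with 0 false calls. With the block these shares were 51.5%, 78.8% and 100%, with 16 false calls among 169. In numbers 1 to 3 there were 3 false calls among 116, and 35 among 173 with the block. Alternatives fixed in advance covered scaling, the test (DESeq2 1.42.0, limma-voom with and without quality weights), filters, thresholds, the block, sex-linked genes, the list test and leaving out each library. Those added after seeing the data were the libraries numbered 1 to 3, leaving out each other number under the block, further tests, scalings, a filter and a length and GC correction under the block, sex read from Xist as a covariate, and the order in which libraries are entered.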

Results

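Cells described as osteoblasts isolated from the calvaria of mice, labelled as a knockout of Sphk2 driven by Osx or as littermate controls, were compared by RNA sequencing. Sphk2 encodes sphingosine kinase 2, which makes sphingosine 1-phosphate, and Osx (osterix, gene Sp7) is a transcription factor of the osteoblast lineage. There were 4 libraries per genotype. The control libraries held 19065421, 17946097, 17410977 and 14571389 counts, and those labelled knockout 15689043, 17928713, 17433571 and 14347495. The study's title places the comparison in the question of how osteoblasts act on neutrophil development.

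Sphk2 did not differ past the threshold between the libraries labelled knockout and the controls, and both means were close. The gene lies on chromosome 7 of GRCm38, from 45709467 to 45718002 on the minus strand. The ratio to the control of the same number was 0.919, 1.13, 0.875 and 0.980 in pairs 1 to 4. Its level was 75.8, 64.2, 82.5 and 133.8 CPM in controls 1 to 4 and 69.7, 72.3, 72.1 and 131.1 CPM in the libraries labelled knockout with the same numbers, from counts of 1123 to 1914. The means were 89.1 ± 30.8 CPM (SD, n = 4) in controls and 86.3 ± 29.9 CPM (SD, n = 4) in the others, and the exact two-sided permutation test gave p = 0.8, where the smallest p possible is 0.0286. The log2 fold change was −0.05 with an SE of 0.30, and −0.04 with an SE of 0.07 when the libraries were paired by number. The paired 95% interval ran from −0.22 to 0.13. The count of the targeted gene therefore does not check the genotype labels, and because counts cover the whole gene they would also include reads outside a deleted part. All directions below are those of the libraries labelled knockout. Sphk1, which encodes the other sphingosine kinase, stood at 7.72 ± 1.41 CPM (SD, n = 4) in controls and 4.59 ± 0.75 CPM (SD, n = 4) in the libraries labelled knockout, with no overlap. Its log2 fold change was −0.75 with an SE of 0.21, its exact permutation p was 0.0286, the smallest possible, and its adjusted p was 0.572 over all genes, 0.0512 with the block and 0.0319 in numbers 1 to 3 alone.

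**Figure D1:**
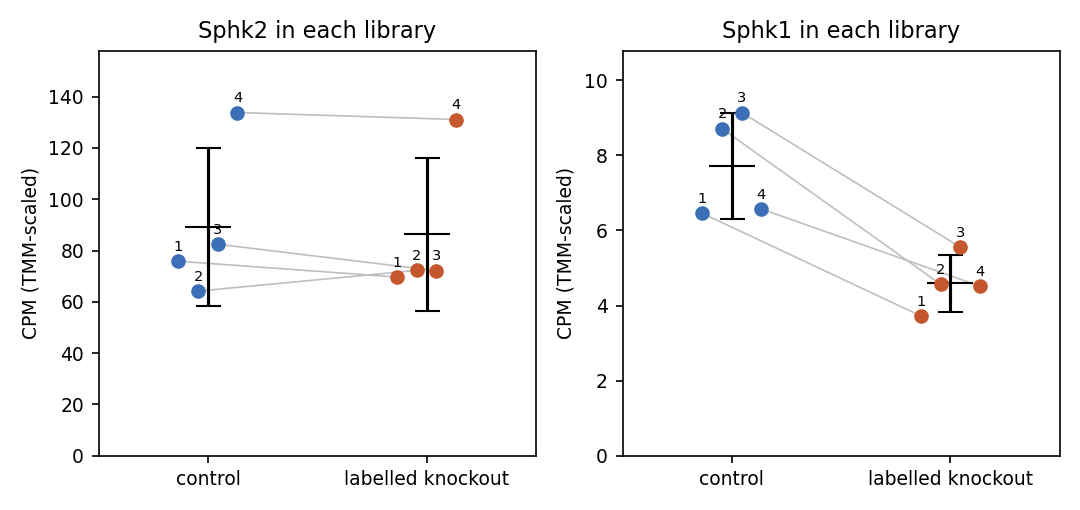
TMM-scaled CPM of Sphk2 (left) and Sphk1 (right) in each library, with lines joining libraries of the same number and black bars for the mean and SD of 4 libraries. Sphk2 overlaps between the groups, from 64.2 to 133.8 CPM in controls and from 69.7 to 131.1 CPM in the libraries labelled knockout, while every Sphk1 value of the libraries labelled knockout lies under every control value.

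Macrophage transcripts were abundant in all 8 libraries. Lyz2, the lysozyme of myeloid cells, was the most abundant gene in each, at 1.69% to 3.30% of the counts, and Apoe was next on average at 13302 ± 2087 CPM (SD, n = 8). Csf1r, the receptor for macrophage colony-stimulating factor, averaged 3912 ± 624 CPM (SD, n = 8). The 27 macrophage and monocyte markers summed to 49572 to 83009 CPM per library, against 4396 to 17461 CPM for the 28 osteoblast markers, which include Col1a1, Col1a2, Sparc and Spp1. Col1a1 alone stood at 907 to 7205 CPM and Col1a2 at 1153 to 6334 CPM. The osteocalcin genes Bglap and Bglap2 of the same list stood at or under 0.58 and 0.98 CPM except in knockout-labelled 1. The osteoblast sum is thus mainly one of collagen and other matrix genes. The 44 collagen and matrix genes summed to less than the macrophage markers except in control 2, where they stood at 50844 CPM against 49572 CPM. The macrophage list did not pass between genotypes (median log2 fold change 0.05, camera adjusted p = 0.439), nor did the osteoblast list (median 0.13, adjusted p = 0.554). Of neutrophil granule genes, Elane and Mpo had at most 1 and 4 counts in a library, while Mmp8, the neutrophil collagenase, stood at 67.1 to 378 CPM and Mmp9 at 5067 and 3923 CPM in control 4 and knockout-labelled 4. Mmp9, also a member of the osteoclast list, stood at or under 52.6 CPM elsewhere. The neutrophil genes Ly6g, S100a8 and S100a9 reached at most 0.11, 3.35 and 0.65 CPM in a library. With these so low, the Mmp8 values are not by themselves a sign of neutrophils.

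**Figure D2:**
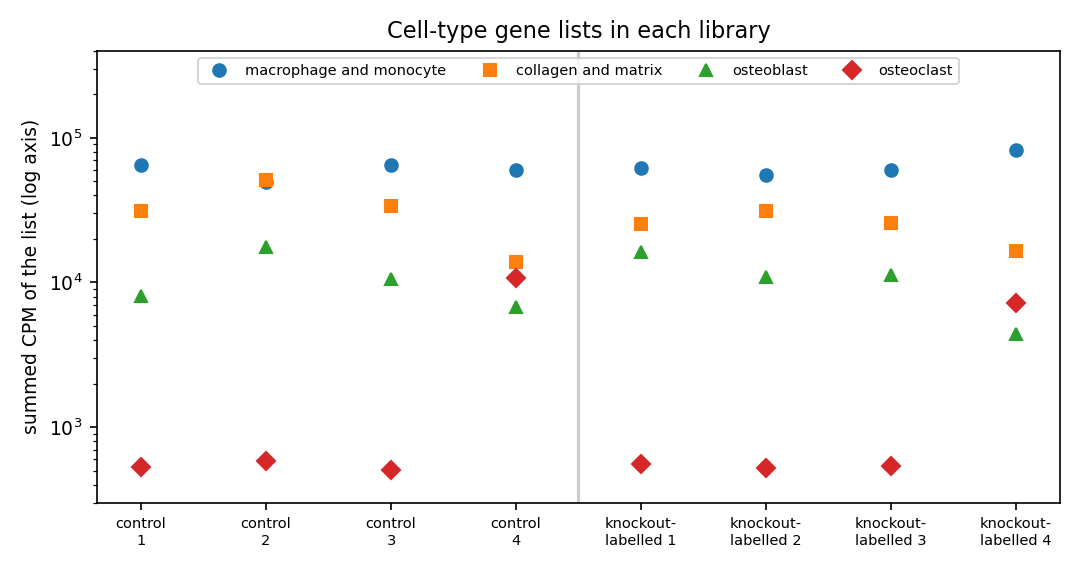
Summed CPM, on a log axis, of 4 marker lists in each library. The macrophage and monocyte list stays between 49572 and 83009 CPM, and the osteoclast list stands at 10784 CPM in control 4 and 7166 CPM in knockout-labelled 4 against 508 to 585 CPM in the other libraries.

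The libraries numbered 4 differed from the rest in both genotypes. The first principal component carried 73.7% of the variance and separated them from all others. In control 4 and knockout-labelled 4, Acp5 stood at 3446 and 1699 CPM against 11.9 to 22.9 CPM elsewhere, and Ctsk at 811 and 711 CPM against 15.2 to 41.7 CPM. Both encode enzymes of bone-resorbing osteoclasts. The collagen and matrix list summed to 13788 and 16523 CPM in them against 25438 to 50844 CPM elsewhere.

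**Figure D3:**
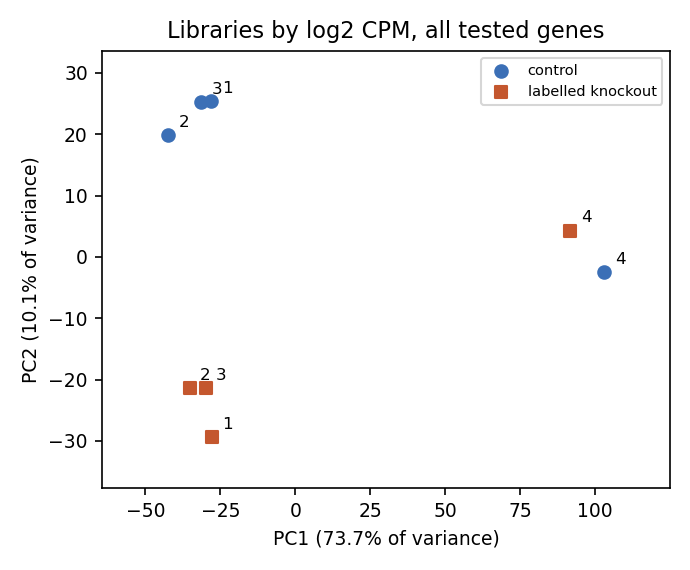
Each point is 1 library placed by the first 2 principal components of log2 CPM, with its number beside it. The first component (73.7% of variance) sets both libraries numbered 4 apart, and the second (10.1%) parts the genotypes among numbers 1 to 3.

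No gene passed the threshold between genotypes. Of 12837 genes tested with edgeR, 0 were higher and 0 lower, the smallest adjusted p was 0.47, and 631 genes had an unadjusted p under 0.05 where 642 would be expected by chance. DESeq2 called 127 higher and 49 lower, limma-voom 0 and 0, and limma-voom with quality weights 1100 and 961. With libraries paired by number, edgeR called 168 genes higher and 151 lower, but 0 and 0 once number 1, 2 or 3 was left out of both groups. Without knockout-labelled 4 the unpaired counts were 17 and 7, without control 4 they were 25 and 13, and with only numbers 1 to 3, chosen after seeing the data, they were 1005 and 812. The median SE of a log2 fold change was 0.25 without the block, 0.10 with it and 0.11 in numbers 1 to 3. The counts of 0 therefore do not show that genes are unchanged.

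The genes nearest the threshold did not pass it, with an adjusted p of 0.47 each. On the higher side were Ncaph, a subunit of condensin (log2 fold change 1.06, SE 0.17), Incenp of the chromosomal passenger complex (0.67, SE 0.11), Mtfr2 (1.43, SE 0.24), the B-cell lectin Cd22 (0.91, SE 0.16) and the spindle protein Nusap1 (1.62, SE 0.28). On the lower side were Olfm1 (−0.92, SE 0.14), the muscle-type adenylosuccinate synthase Adssl1 (−0.62, SE 0.11), the adhesion molecule L1cam (−0.91, SE 0.17), the histidine ammonia-lyase Hal (−2.96, SE 0.58) and Rps7 (−0.63, SE 0.13). All except Nusap1 and Hal passed with the block.

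With libraries paired by number, the largest rises were in Depdc1b (log2 fold change 2.06, SE 0.33), the activity-regulated gene Arc (2.05, SE 0.27), the endothelin receptor Ednrb (1.79, SE 0.29), Ankle1 (1.63), Slco2b1 (1.62), the DNA repair gene Fancd2 (1.53), Ano3 (1.53), Mtfr2 (1.47), Rtn4rl1 (1.45) and the cytokinesis factor Ect2 (1.41), with adjusted p of 0.030 to 0.043. The largest falls were in the cytokine Il11 (−2.31, SE 0.42), Sema3d (−1.82, SE 0.30), the chemokine Ccl5 (−1.51), Ifitm6 (−1.32), the chemokine receptor Ccr1 (−1.30), Sema6c (−1.25), the lymphatic growth factor Vegfc (−1.22), Cdh13 (−1.16), Slc6a12 (−1.16) and the growth hormone receptor Ghr (−1.15), with adjusted p of 0.036 to 0.050. The choice required one direction in 4 of 4 pairs, and in pair 4 it rests on at most 24 counts in a library for 8 of these 20 genes, Arc, Ednrb, Slco2b1, Ano3, Rtn4rl1, Il11, Sema3d and Cdh13. Ccl5, Ifitm6, Vegfc and Slc6a12 stood at or under 2.36 CPM in numbers 1 to 3, and their unpaired fold changes turned positive when control 4 was left out.

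Cell-cycle genes were higher as a group. All 38 had a positive log2 fold change, with a median of 0.97, and camera gave an adjusted p of 1.47e-46, or adjusted p = 0.18 with an estimated correlation. Over all genes 0 passed, and 29 rose when adjusted over the list alone. With the block 4 rose over all genes, Aurkb, Kif23, Pcna and Prc1, and 36 when adjusted over the list alone, and in numbers 1 to 3 alone 30 rose. Mki67, a marker of dividing cells, stood at 99.6 to 162 CPM in controls and at 451, 477, 451 and 189 CPM in the libraries labelled knockout. Its log2 fold change was 1.62 with an SE of 0.31. Kif23 (1.24, SE 0.23) and Kif11 (1.48, SE 0.30), motor proteins of the spindle, were not past the threshold without the block. In pair 4 the list's median difference was 0.21, against 1.64, 0.92 and 1.27 in pairs 1 to 3.

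Cytosolic ribosomal protein genes were lower as a group. None of the 57 tested had a positive log2 fold change, the median was −0.47, and camera gave an adjusted p of 8.70e-39, or adjusted p = 0.39 with an estimated correlation. The direction held under every scaling tried, with medians of −0.44 to −0.47 without a block. Over all genes 0 passed, and 5 fell when adjusted over the list alone, among them Rpl4, Rpl12, Rpl32 and Rps7. With the block 36 fell over all genes and 55 when adjusted over the list alone. Rpl12 (−0.51, SE 0.11) and Rpl32 (−0.59, SE 0.13) are examples, and Rpl32 stood at 392 to 413 CPM in controls and 238 to 332 CPM in the libraries labelled knockout. The summed CPM of the list was also higher in the libraries numbered 4 than in the rest of each group.

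**Figure D4:**
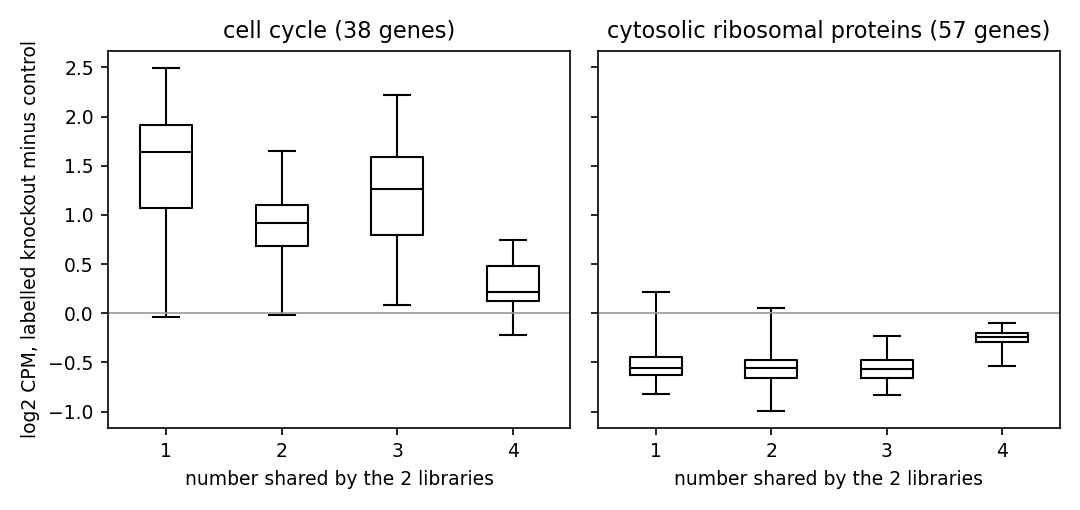
Difference in log2 CPM, labelled knockout minus control, for each tested member of the cell-cycle list (38 genes, left) and the cytosolic ribosomal protein list (57 genes, right) within each numbered pair. Boxes show quartiles, lines the median and whiskers the full range. Medians are positive in all 4 pairs on the left and negative in all 4 on the right, and smallest in pair 4 in both lists.

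Immediate early and dissociation genes were lower, with 4 of 26 positive, a median of −0.32 and a camera adjusted p of 4.07e-05 (adjusted p = 0.18 with an estimated correlation). Their median was −0.50, −0.56 and −0.40 in pairs 1 to 3 but 0.14 in pair 4, where 15 of 26 were higher. Members over all genes and over the list alone numbered 0 past the threshold, and with the block Myc (−0.65, SE 0.07) and Klf4 (−0.89, SE 0.13) fell. Jun (−0.28, SE 0.10) and the heat shock gene Hspa1a (−0.58, SE 0.23) were not past it. Cholesterol and fatty acid synthesis genes were higher, with 24 of 29 positive, a median of 0.20 and an adjusted p of 0.00033 (adjusted p = 0.59 with an estimated correlation), and 0 members passed over all genes or over the list alone. Hmgcs1, an early enzyme of the mevalonate pathway, rose with the block (0.36, SE 0.05), while Fdps (0.28, SE 0.11), Scd2 (0.73, SE 0.33) and Tm7sf2 (0.30, SE 0.17) did not pass. This list's call was lost without control 4.

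Unfolded protein and integrated stress response genes were higher, with 24 of 28 positive, a median of 0.20 and a camera adjusted p of 0.00021 (adjusted p = 0.66 with an estimated correlation). Their median was 0.40, 0.27 and 0.31 in pairs 1 to 3 but −0.089 in pair 4, where 20 of 28 were lower. No member passed over all genes or over the list alone. The chaperones Hspa5 (0.49, SE 0.21) and Hsp90b1 (0.40, SE 0.16) and the amino acid transporter Slc7a5 (0.65, SE 0.32) had positive values, whereas the cystine transporter Slc7a11 was at −1.61 with an SE of 0.38. With the block only Slc7a5 passed, and the list's call was lost without knockout-labelled 4. The neutrophil list, of which 11 of 35 genes were expressed enough to test, was lower with a median of −0.39 and an adjusted p of 0.0026 (adjusted p = 0.39 with an estimated correlation), and its call was lost with the block (adjusted p = 0.0716), with DESeq2 (0.0574) and with no filter on low counts (0.138). Its median was −1.15, −0.88 and −1.46 in pairs 1 to 3 but 0.30 in pair 4, where 9 of 11 were higher. With the block Csf3r, the receptor for the neutrophil growth factor and named after its value was seen, rose (0.30, SE 0.06). The list shares Mmp9 with the osteoclast list. Its leading members were Mmp8 (−1.16, SE 0.46), Fpr1 (−0.70, SE 0.38), Anxa1 (−0.31, SE 0.16) and Ly6c2, which had at most 1.27 CPM, and of these Fpr1 and Anxa1 are also expressed by macrophages. Counts per library do not show which cells held Mmp8, so the list's call is not a measure of neutrophils.

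With all 8 libraries, neither the sphingolipid list nor the haematopoietic niche list passed, with or without the block. Of 34 sphingolipid genes tested, 0 passed over all genes or over the list alone (median −0.06, adjusted p = 0.19). With the block Ugcg, glucosylceramide synthase, fell (−0.73, SE 0.07), while Kdsr (−0.51, SE 0.13) and Sgms1 (−0.37, SE 0.14) did not pass. Of 31 niche and neutrophil factors the median was −0.05 (adjusted p = 0.17), with 0 past over all genes and 1 lower when adjusted over the list alone, the cytokine Il11. With the block Il11 and the Notch ligand Jag1 (−0.87, SE 0.09) fell, and Il34 (−0.78, SE 0.27) and Ccl2 (0.39, SE 0.13) did not pass. Cxcl12, which retains neutrophils in bone marrow, differed by −0.08 with an SE of 0.49, Runx2 by −0.22 with an SE of 0.31 and Sp7 by −0.23 with an SE of 0.70, each with overlapping groups, and with the block Cxcl12 and Sp7 were at 0.02 and 0.03. Csf3, the neutrophil growth factor, was too low to test, with at most 14 counts in a library. Among osteoblast genes, Enpp1 rose with the block (0.43, SE 0.08), and Bglap2, Ibsp and Phospho1 did not pass. Of the macrophage genes Ms4a7 rose with the block (0.32, SE 0.06), and Apoe (0.33), Laptm5 (0.22) and C1qa (−0.21), given with the block, did not pass.

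With libraries paired by number, 12 of 30 lists passed under camera, of which 0 passed with an estimated correlation. Beyond those above they were higher values in the adipocyte lineage list (adjusted p = 0.031) and the senescence and p53 list (0.026), and lower values in collagen and matrix (0.015), osteoclast (0.0498), nuclear-encoded oxidative phosphorylation (0.0041), BMP and TGF-beta (0.026) and NF-kappaB (0.0498) lists. With an estimated correlation their adjusted p were 0.57 to 0.80. For none of these 7 lists did the median go one way in 4 of 4 pairs. The oxidative phosphorylation median lay between −0.017 and 0.036 in pairs 1 to 3 and was −0.36 in pair 4, and without pair 4 neither this list (adjusted p = 0.701) nor the osteoclast list (0.952) passed. In pair 4 the BMP and TGF-beta median was 0.47, with 22 of 28 higher, and the senescence and p53 median −0.26, with 14 of 18 lower. Past the threshold over all genes with the block were Sesn1 of the p53 list (0.49), Ccl5 of the NF-kappaB list, and Id2 (0.47), Tgfbi (−0.39), Pmepa1 (−0.72) and Inhba (−0.66) of the BMP and TGF-beta list, the last 3 lower. The osteoclast members Nfatc1, Itgb3, Atp6v0d2 and Dcstamp did not pass with or without the block in all 8 libraries. In numbers 1 to 3 alone Atp6v0d2 rose (0.97, adjusted p = 0.014, and 0.95, adjusted p = 0.0046 with the block), while 2 other members of the list fell. The list's median there was 0.058, or 0.096 with the block, so its lower direction is that of all 8 libraries.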

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

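The tests of Sphk2, of the osteoclast, macrophage and collagen lists, of length and GC and of culture labels, and the split counts for genes without a block and for lists in numbers 1 to 3, were chosen after the result was seen, while the predictions for the other split counts and for the thinning of counts were written before those tests were run, though after the gene and list counts were seen and partly on numbers 1 to 3 and on number 4, which were set apart after the data were seen.

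Sphk2 did not differ past the threshold in the libraries labelled knockout, and at 131 CPM in knockout-labelled 4 it stood far above the 69.7 to 72.3 CPM of the other libraries of its group. The test of labels exchanged within 1 numbered pair took a knockout to hold Sphk2 at 0.5 of control or less. An exchange would then leave 3 such pairs, but the lowest ratio was 0.875. The ratios cannot decide on an exchange, because a true knockout could keep its whole-gene count for the reasons that follow. Reads from cells in which the knockout does not act could fill the gene, since macrophage markers summed on average to 5.82 times the osteoblast markers, and reads outside a deleted part could do the same under a paired lower limit of −0.22. These cannot be told apart with counts per gene, because counts per exon were not analysed here and counts are not given per cell type. Cells isolated otherwise than described, samples taken from outside the numbered pairs, and labels wrong in 1 or more pairs, stay open.

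The libraries numbered 4 differed from the rest in both genotypes, with 4419 genes higher and 4342 lower of 12837 tested, a split by shared number that was looked at after the principal components were seen. Lower depth is argued against, since after thinning every library to the smallest total 98.1% of those genes were called again in the same direction. A loss of mesenchymal cells alone is argued against, since it would raise osteoclast and macrophage genes alike and their medians differed by 4.23 on the log2 scale. More osteoclast-lineage cells may be part of it, since the osteoclast list's median difference was 4.56, but a changed state of the same cells would give the same value. No biological explanation from the design was tested, because number is not a group of the study.

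Cell-cycle genes were higher and ribosomal protein genes lower in the libraries labelled knockout. Trends with transcript length and GC are argued against as the whole cause, since the smaller of the 2 shares of the medians kept after correction was 90.8%, although the ribosomal median went from −0.48 (median SE 0.078) to −0.44 (median SE 0.089) and its calls from 36 to 10 with that smaller change and larger error. The medians of the macrophage list (0.12, SD 0.32) and the collagen list (−0.18, SD 0.39) each lay below the cell-cycle median of 1.03 by more than their SD. This argues only against a larger share of macrophages or mesenchymal cells that raised its own markers as much as the cell-cycle genes. Smaller changes in share stay open, and the ribosomal protein median was not compared. Culture conditions and genotype cannot be told apart, since 0 labels give a culture day or plate. An effect of genotype is one open explanation and was not tested separately.

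Other splits of the libraries were counted. Without a block, 35 of 35 splits gave at least the real 0 genes (highest other 0), which decides nothing because no split can give fewer. For lists 33 of 35 gave at least the real 6 lists (highest other 19), so chance cannot be excluded for the lists. With the block, 8 splits part all pairs, too few for a share under 0.05. For genes 2 of 8 gave as many, the real 319 and 356 when the labels of pair 4 are exchanged, and the other 6 splits gave 0. For lists 5 of 8 gave as many (real 12, highest other 15). In numbers 1 to 3, 10 splits are too few for a share under 0.05, and 1 of 10 gave as many genes (real 1817, highest other 0) and 4 of 10 as many lists (real 10, highest other 15).

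In 44 of 162 groups of 4 libraries 1 library stood far from the other 3. Chance would give about 1 in 20, or 8.1 groups, if the groups were independent. They are not, since the genes move together and were partly chosen from these data, so that rate is no measure of the excess. In 38 of the 44 groups the library standing apart was numbered 4. Among osteoclast genes these were Nfatc1 at 209.8 CPM in control 4, Itgb3 at 122.6 CPM in control 4 and 89.0 CPM in knockout-labelled 4, Atp6v0d2 at 321 and 124 CPM and Dcstamp at 65.7 and 35.3 CPM in the same libraries. Summed CPM was 10784 and 7166 for the osteoclast list and 7077 and 5979 for the neutrophil list, which shares Mmp9 with it, in control 4 and knockout-labelled 4, and 26153 for ribosomal proteins in knockout-labelled 4. Ccl5 stood at 167 and 57.9 CPM, Ifitm6 at 114 and 45.1 CPM, Vegfc at 31.5 and 11.8 CPM, Slc6a12 at 66.6 and 31.3 CPM, Ano3 at 0.350 and 0.437 CPM and Csf3 at 0.350 and 1.02 CPM in control 4 and knockout-labelled 4. In control 4 alone Ankle1 stood at 5.87 CPM, Ghr at 9.86 CPM, Enpp1 at 16.4 CPM, Jag1 at 16.3 CPM and Hspa5 at 726 CPM. In knockout-labelled 4 alone Nusap1 stood at 26.6 CPM, Ect2 at 15.3 CPM, Mki67 at 189 CPM, Rps7 at 400.2 CPM, Rpl32 at 332 CPM, Ccr1 at 75.2 CPM, Fpr1 at 102 CPM and Ly6c2 at 0.728 CPM. In knockout-labelled 1 the bone matrix genes Ibsp at 1082 CPM and Bglap2 at 40.7 CPM and the mineralization gene Phospho1 at 7.32 CPM stood above the rest of the group. Sema6c at 2.50 CPM and Sgms1 at 41.0 CPM in knockout-labelled 2, and L1cam at 4.22 CPM in knockout-labelled 3, stood above theirs.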

How the results depend on the processing

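Alternatives with the block in addition to another change, those on numbers left out of both groups, sex as a covariate and the entry order were chosen after the result was seen, and the others were planned. The counts of 0 higher and 0 lower genes stayed 0 under every scaling, filter and threshold tried without the block, without X and Y genes, with limma-voom, with sex as a covariate, and with the block once number 1, 2 or 3 was left out. Elsewhere the higher and lower counts were 127 and 49 with DESeq2 Wald test, 1100 and 961 with limma-voom with quality weights, 168 and 151 with the block alone, 1005 and 812 with libraries numbered 1 to 3, 1593 and 1539 with libraries numbered 1 to 3 and the block, 541 and 404 with DESeq2 Wald test and the block, 349 and 281 with limma-voom and the block, 157 and 149 with DESeq2-type size factors (RLE) and the block, 186 and 162 with upper-quartile factors and the block, 206 and 159 with library size only and the block, 164 and 146 with at least 1 CPM in 4 libraries and the block and 111 and 91 with length and GC correction and the block. Leaving out 1 library gave 0 to 25 higher and 0 to 13 lower. The causes were not tested, but 3 pairs gave 0 calls where they included pair 4 and 1593 and 1539 without it, so number of pairs alone does not set the count. In simulated counts the last of these fits made 35 false calls among 173.

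The 6 lists became 12 with limma-voom with quality weights, 12 with the block alone, 0 with camera with an estimated correlation, 0 with fry, directional, 10 with libraries numbered 1 to 3, 13 with libraries numbered 1 to 3 and the block, 11 with numbers other than 1 and the block, 10 with numbers other than 3 and the block, 12 with DESeq2 Wald test and the block, 10 with DESeq2-type size factors (RLE) and the block, 12 with upper-quartile factors and the block, 14 with library size only and the block and 11 with at least 1 CPM in 4 libraries and the block, and 6 to 17 when 1 library was left out. The cause was not tested. With an estimated correlation the count was also 0 with the block alone and in numbers 1 to 3 with or without it. Fry, in the order of libraries used, gave 1 with the block alone, 10 in numbers 1 to 3 and 7 there with the block. Without the block, scaling left the count at 6. The block changed the calls given in the report with their blocked values and no other list or named gene call.

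Of 2281 combinations of 72 named genes and a setting, 1709 kept direction and side of the threshold, 515 kept direction and passed it and 57 reversed, and no call could be lost because no named gene passed at the start. Some of these genes were chosen because they passed with the block, so part of the 515 was fixed by that choice. Reversed log2 fold changes, Sphk2 included, were as follows, and the cause was not tested. Of these only Atp6v0d2 in numbers 1 to 3, with and without the block, passed the threshold. With limma-voom, Atp6v0d2 0.42, Cxcl12 0.035 and Sp7 0.12. With limma-voom with quality weights, Atp6v0d2 1.04, Cxcl12 0.22 and Nfatc1 0.023. With the block alone, Atp6v0d2 0.21, Cxcl12 0.025 and Sp7 0.032. With libraries numbered 1 to 3, Atp6v0d2 0.97 and Nfatc1 0.012. With libraries numbered 1 to 3 and the block, Atp6v0d2 0.95, Cxcl12 0.053 and Nfatc1 0.013. With numbers other than 1 and the block, Atp6v0d2 0.035 and Ibsp −0.054. With numbers other than 2 and the block, Atp6v0d2 0.16, Cxcl12 0.17 and Sp7 0.52. With DESeq2 Wald test and the block, Atp6v0d2 0.39, Cxcl12 0.023 and Sp7 0.14. With DESeq2-type size factors (RLE) and the block, Atp6v0d2 0.21, Cxcl12 0.019 and Sp7 0.027. With upper-quartile factors and the block, Atp6v0d2 0.22, Cxcl12 0.037 and Sp7 0.0496. With library size only and the block, Atp6v0d2 0.25, Cxcl12 0.058 and Sp7 0.074. With at least 1 CPM in 4 libraries and the block, Atp6v0d2 0.21, Cxcl12 0.025 and Sp7 0.033. With length and GC correction and the block, Atp6v0d2 0.17, Cxcl12 0.0067, Sp7 0.051 and Sphk2 0.0036. With sex as a covariate, Atp6v0d2 1.44, Ccl5 2.63, Dcstamp 0.86, Ifitm6 2.08, Slc6a12 1.85 and Sphk2 0.047. With limma-voom and the block, Cxcl12 0.0066. With numbers other than 3 and the block, Sp7 0.28 and Sphk2 0.0052. Leaving out 1 library, the values that reversed ran for Atp6v0d2 from −2.70 to 2.59, Ccl5 from −6.56 to 3.54, Cxcl12 from −0.39 to 0.46, Dcstamp from −5.12 to 1.93, Ifitm6 from −5.66 to 3.03, Nfatc1 from −0.46 to 0.0016, Runx2 from −0.41 to 0.037, Slc6a12 from −5.18 to 2.81, Sp7 from −0.60 to 0.14, Sphk2 from −0.32 to 0.21 and Vegfc from −3.48 to 1.01. Depth limits Csf3, which was too low to test.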

Other observations

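All comparisons in this part were chosen after the values were seen. In control 4 and knockout-labelled 4, 20 of 21 antigen presentation genes (median log2 difference 1.45) and 17 of 28 NF-kappaB and inflammatory genes (median 1.46, with 3 lower) were higher than in the other libraries, with camera adjusted p of 7.97e-08 and 0.00152, or adjusted p = 0.366 and 0.440 with an estimated correlation. Among single genes Saa3, an acute-phase protein, stood at 776 and 807 CPM against at most 5.77 CPM, complement C3 at 3157 and 2772 CPM against 24.0 to 62.4 CPM, and Cd74, the invariant chain of class II presentation, at 704 and 2996 CPM against 25.1 to 45.9 CPM. Of 28 glycolysis and hypoxia genes 26 were higher (median log2 difference 1.86), and of 49 nuclear-encoded oxidative phosphorylation genes 49 were higher (median 1.20). Of 23 Wnt genes 15 were lower (median −1.67), and of 28 BMP and TGF-beta genes 24 (median −1.89). Camera adjusted p for the last 4 lists were 6.02e-11, 4.58e-16, 6.83e-04 and 4.76e-05, and 0.311, 0.440, 0.366 and 0.440 with an estimated correlation. The scavenger receptor Lrp1 stood at 384 and 377 CPM against 4372 to 4774 CPM.

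Some genes of mineralizing bone cells stood higher in knockout-labelled 1 than in any other library, though the summed osteoblast list was higher in control 2 (17461 against 16333 CPM) and the summed osteocyte list in control 4 (1704 against 1083 CPM). Alpl stood at 83.6 CPM there against 1.46 to 30.6 CPM in the other 7 libraries, Bglap at 42.3 CPM against at most 0.582 CPM, Dmp1 at 13.7 CPM against at most 0.778 CPM and Phex at 9.80 CPM against at most 0.556 CPM, while Ifitm5 at 2.67 CPM was below the 3.36 and 3.20 CPM of control 4 and knockout-labelled 4. Xist, expressed from the inactive X chromosome of female cells, stood at 729 to 1338 CPM in controls 1 and 2 and knockout-labelled 1, 2 and 4, and at or under 0.611 CPM in controls 3 and 4 and knockout-labelled 3, so pair 4 holds unlike sexes. The Y-linked gene Ddx3y stood at 44.6 to 103 CPM in those last 3 libraries, and in control 1 it had 2.91 CPM beside Xist at 1252 CPM.

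For the hypothesis that the differences of numbers 1 to 3 also occur in pair 4, 55.1% of the genes called in those numbers (995 of 1805) had the same direction in pair 4, which leaves it open, against 50.4% of genes with an unadjusted p over 0.5. The share was 62.2% of the higher calls (620 of 996) and 46.4% of the lower calls (375 of 809). Their median log2 differences in pair 4 were 0.089 and 0.032. The higher calls leaned the way the hypothesis predicts. The lower calls did not. Their share was below the 50.4% of genes with an unadjusted p over 0.5, and their median was positive where a fall was predicted. That median lay near the 0.014 of all tested genes, and signs in 1 pair cannot decide the question for them. Of 10 lists called in numbers 1 to 3, a count that 4 of 10 splits of these libraries reach, 0 passed with an estimated correlation. In pair 4, 3 of the 10 had a median of the same direction, the cell-cycle, ribosomal protein and cholesterol lists. The sizes of the other medians ran from 0.0025 (NF-kappaB) to 0.47 (BMP and TGF-beta). A count of 3 of 10 is fewer than the hypothesis predicts, but signs in 1 pair cannot decide it for the lists at large. For the cell-cycle list 86.8% of members (33 of 38) and for ribosomal proteins 57 of 57 had the same direction, as the hypothesis predicts for these lists. All 49 oxidative phosphorylation genes were also lower in pair 4 (median −0.36), although their medians in pairs 1 to 3 lay between −0.017 and 0.036. A fall of every member in pair 4 is thus not particular to lists that fell in numbers 1 to 3. Members of a list move together, and pair 4 is 1 observation with unlike sexes.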
